A study of Arabidopsis thaliana
Meloidogyne incognita and Arabidopsis thaliana and Meloidogyne incognita with 15 samples.

How the data were processed

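Small RNA was sequenced from Arabidopsis thaliana (ecotype Wassilewskija) root galls formed by the root-knot nematode Meloidogyne incognita, from uninfected root internodes cut at the same times, and from nematode juveniles (J2, the stage that infects roots). Per the labels, seedlings 25 days old received 200 sterilised J2 each, galls were taken 7 and 14 days post inoculation (dpi), about 150 galls or root pieces were ground per sample, and 2 µg of total RNA went into a SOLiD small RNA library with 11 and then 4 PCR cycles and a size selection of 115 to 130 nt. Each of the 5 groups had 3 libraries, 15 in all, which the labels call independent biological replicates for the plant conditions. For the J2 libraries no label states separate cultures, so their p-values measure the spread between those libraries, which may be technical.

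The authors deposited raw read counts per small RNA feature, with 1 column per library and no normalisation. The values were whole numbers with a different total in each column. The submitters' processing notes name the TAIR10 genome build and Picard, without a role or a version. The aligner, the counting program, the read lengths and the treatment of reads that match several features are not given in the sources used here. There were 1036 rows in each of 2 tables: 658 tRNA genes, 296 miRNA hairpins, 46 rows typed as pseudogenes, 33 typed as known non-coding RNA and 3 Caenorhabditis elegans miRNA spike-ins. By overlap with the TAIR10.1 RefSeq annotation, whose nuclear chromosomes have the same sequence as TAIR10, 44 of the pseudogene rows were snoRNAs and 2 were rRNAs, and the known rows held 25 snoRNAs, 3 snRNAs, 3 rRNAs and 2 rows without a match. All 296 hairpins had the start and end of an annotated MIR gene, and 47 of them lay in an exon of a protein-coding gene. Strand handling is not given, so reads of such a hairpin and of its host cannot be told apart. Several rows with the same sequence held the same counts, and many hairpins of a family share 1 mature miRNA sequence, so values of single copies within a family are uncertain.

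The 7 dpi plant libraries and the J2 libraries came in 1 table and the 14 dpi libraries in the other, so day and table coincide. Levels were therefore never compared between the days. Galls were compared with roots within a table, and only these gall effects were set against each other, in an interaction fit over both tables. The samples' titles, source names and characteristics gave the day used here, and the free-text descriptions gave the opposite day. A swap would exchange the day of every gall and root library together and would leave each gall against root contrast as it stands, under the other day. It would turn the sign of every difference between the days, and the J2 libraries would stand against roots of 14 dpi.

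Total counts without the spike-ins ranged from 5218083 to 13957677 in the plant libraries and from 77650 to 221736 in the J2 libraries. Levels are given as CPM, the count of a row scaled to library size. In plant libraries that size was the total multiplied by a trimmed mean of M values (TMM) factor, fitted within each day. These factors ran from 0.841 (root replicate 1, 7 dpi) to 1.12 (gall replicate 3, 14 dpi). In J2 libraries the size was the total alone, so J2 and plant CPM given side by side are on different scales. PCR reads without molecular identifiers are not independent molecules, so counting error understates the error of a single library, and errors are given as the SD over 3 libraries or as the standard error (SE) of a fitted log2 fold change. Within a group no libraries held identical values, and the chi-square per degree of freedom between libraries of 1 group was at least 41.7, so no library was taken for a copy of another; this does not tell technical from biological repeats.

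Galls and roots were compared with edgeR 4.0.16 in R 4.3.3: trimmed mean of M values (TMM) scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, negative binomial dispersions and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over all rows tested and a threshold of 0.05. The difference of the gall effect between the days was an interaction term over the 12 plant libraries. The J2 libraries were compared with the 7 dpi roots after scaling by total counts alone. Lists of miRNA families were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between rows and again with an estimated one, and with fry, with Benjamini-Hochberg adjustment over 13 lists. The lists covered developmental timing (MIR156, MIR157, MIR172), auxin (MIR160, MIR164, MIR167, MIR390, MIR393), MYB and TCP factors (MIR159, MIR319), growth and meristems (MIR165, MIR166, MIR170, MIR171, MIR394, MIR396), the silencing machinery (MIR162, MIR168, MIR403), phosphate (MIR399, MIR778, MIR827, MIR2111), sulfate (MIR395), nitrogen (MIR169, MIR826, MIR5090), copper (MIR397, MIR398, MIR408, MIR857), triggers of secondary siRNAs (MIR161, MIR173, MIR400, MIR828), immunity (MIR163, MIR393, MIR472, MIR773, MIR825, MIR844, MIR863), young miRNAs made by DCL4 (MIR822, MIR839, MIR869) and fragments of structural RNA (rRNA, tRNA, snoRNA, snRNA). A list of animal miRNAs and a list of TAS loci had 0 rows in the tables and were not tested. MIR393 stood in both the auxin and the immunity list. Shares of RNA classes were compared with 2-sided exact permutation tests.

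The groups, tests, lists, alternatives and the rule for named rows were fixed before the data were examined. Named rows were, for each gall against root comparison, the 12 rows of lowest p in each direction among those past the threshold, up to 10 rows past it on both days in 1 direction, the 5 rows of lowest p for the difference of days, the 10 rows of highest mean CPM in J2, all MIR159 and MIR319 rows, and up to 4 members of each list with the lowest p. Where another row is named, the text says that it was chosen after its values were seen. The alternatives were relative log expression, total count and upper quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a mean count of at least 50, rows summed per family, the row with the most counts left out, rows whose J2 CPM exceeded 10 percent of the gall CPM left out, all 12 plant libraries in 1 fit, a replicate block, and each library left out in turn. A fit to miRNA rows alone, scaled among themselves, was added after seeing the data.

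The scripts were tested on simulated counts drawn from the means and library sizes of these libraries. Each row was drawn independently around its mean over the groups, and randomly picked rows were raised or lowered with equal probability. The shares recovered and false calls therefore do not measure errors from reads shared between copies, or from scaling when most changes go 1 way. At 7 dpi, 45.8% of 96 rows changed by 1 on the log2 scale and 99.0% of 103 rows changed by 2 were recovered among 1006 rows, with 6 false calls. At 14 dpi the shares were 40.9% of 93 and 98.1% of 105 among 987 rows, with 5 false calls. For the difference of days they were 12.5% of 104 and 78.9% of 95 among 1007 rows, with 2 false calls, and for J2 against roots 1.96% of 102 and 30.6% of 98 among 1008 rows, with 1 false call. The spike-in rows were left out of library totals, scaling and tests because no label gives the amounts added. Figures were drawn with matplotlib 3.10.9 under Python 3.11.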

Results

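Small RNA counts were compared between galls that Meloidogyne incognita induced on Arabidopsis roots and uninfected root internodes, at 7 and 14 dpi, with libraries of the nematode's J2 juveniles alongside. There were 3 libraries in each of the 5 groups. Total counts at 7 dpi were 11715234, 9461950 and 10539160 in root replicates 1 to 3 and 11145621, 9840197 and 9774254 in the galls. At 14 dpi they were 5218083, 8676659 and 8239302 in roots and 6316145, 13957677 and 6957841 in galls. The J2 libraries held 221736, 77650 and 82035 counts on these Arabidopsis rows; whether few reads or few matching features made these totals low was not tested. The RNA integrity numbers on the labels lay between 8 and 10. They were lowest in gall replicate 1 of 14 dpi (8) and root replicate 2 of 7 dpi (8.3).

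miRNA hairpins took 26.3 ± 2.68% of the counts in galls and 29.1 ± 5.66% in roots at 7 dpi (SD, n = 3 each), and 23.5 ± 4.16% against 17.3 ± 4.40% at 14 dpi. tRNA genes took 55.3 ± 5.35% against 52.8 ± 8.17% at 7 dpi and 60.6 ± 5.67% against 66.1 ± 6.60% at 14 dpi. The 8 class shares tested gave exact 2-sided permutation p-values of 0.2 or more with n = 3, where the smallest possible is 0.1, and Benjamini-Hochberg adjusted values of 0.686 or more. Root replicate 2 at 7 dpi carried 61.9% tRNA counts, beside 45.9% and 50.7% in the other root libraries of that day, and gall replicate 1 carried 61.4%, beside 53.3% and 51.2%. At 14 dpi root replicate 3 stood apart with 73.5% tRNA and 12.3% miRNA counts. Root replicates 1 and 2 held 60.8% and 63.9% tRNA and 19.8% and 19.97% miRNA counts. Gall replicate 1 of 14 dpi carried 66.8% tRNA counts, beside 59.2% and 55.7% in gall replicates 2 and 3. The integrity numbers of these tRNA-rich libraries were 8.3 and 8.8 at 7 dpi and 8.8 (root) and 8 (gall) at 14 dpi. In each group but the 7 dpi galls, no library had a lower number. Whether RNA quality bears on the tRNA counts or on the calls was not tested.

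The comparison at 7 dpi asked which small RNAs differ between young galls and root tissue of the same age. The hairpins of miR390, which starts the production of siRNAs against auxin response factors, rose: MIR390a (chromosome 2, 16061954 to 16062060, TAIR10) went from 770.3 ± 386 CPM in roots to 5306 ± 1618 CPM in galls (SD, n = 3 each), a 6.89-fold rise, and MIR390b (chromosome 5, 23636947 to 23637066) rose 4.96-fold to 3303 ± 735 CPM. MIR5643b (chromosome 5, 11757140 to 11757222) rose 6.44-fold, from 38.6 ± 10.9 to 249 ± 17.8 CPM, and MIR775 (chromosome 1, 29422452 to 29422574) rose 3.73-fold, from 77.4 ± 26.7 to 289 ± 33.5 CPM. Among rare hairpins, MIR2937 rose from 1.48 ± 0.491 to 16.9 ± 6.17 CPM and MIR4243 from 0.357 ± 0.227 to 4.00 ± 0.273 CPM. MIR5020c (chromosome 2, 4770538 to 4770646) fell from 34.7 ± 17.5 to 4.25 ± 0.344 CPM, a log2 change of −3.03. In each of these rows all 3 gall libraries lay on the same side of all 3 root libraries, as 10% of rows would by chance. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 change of MIR390a was 2.78 (SE 0.41, adjusted p = 0.000449) and that of MIR5643b was 2.69 (SE 0.32, adjusted p = 0.000137). The MIR5020c call was lost without gall replicate 1 (log2 −2.88, adjusted p = 0.0542 by the same edgeR test). The mature miR390 of both loci has the same sequence, and so have the mature miRNAs of MIR5643a and MIR5643b, so the split between copies is uncertain. Stretches of 21 nt in MIR5643b occur at a median of 21 places in the genome, and those in MIR5643a at 83, so reads from other repeat loci are not excluded.

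Of 1009 rows tested at 7 dpi, 83 passed the threshold, 55 higher and 28 lower in galls, and 226 had an unadjusted p under 0.05. They comprised 41 higher and 21 lower of 274 miRNA hairpins, 11 higher and 7 lower of 658 tRNA genes, and 3 of 67 snoRNAs, all 3 higher. The tRNA rows that fell included the plastid Met_e-CAT-13, from 235 ± 84.2 to 74.0 ± 22.3 CPM, and Cys-GCA-16, from 126 ± 54.0 to 40.2 ± 4.22 CPM. The number of calls over all rows was 75 without root replicate 1, 176 without root replicate 2, 39 without root replicate 3, 19 without gall replicate 1, 72 without gall replicate 2 and 17 without gall replicate 3. Hairpins higher numbered 24 without root replicate 3, 17 without gall replicate 1 and 15 without gall replicate 3, and hairpins lower 49 without root replicate 2, 6 without root replicate 3, 1 without gall replicate 1 and 2 without gall replicate 3. snoRNA calls numbered 7 without root replicate 2, 1 without root replicate 1 or gall replicate 1 and 0 without gall replicate 3. The tRNA calls numbered 8 without root replicate 1, 66 without root replicate 2, 6 without root replicate 3, 1 higher and 17 lower without gall replicate 2, and 0 without gall replicate 1 or gall replicate 3, where the edgeR adjusted p of Met_e-CAT-13 was 0.120 and 0.0769 and that of Cys-GCA-16 was 0.0887 and 0.0690. Of the calls, 66.3% were higher in galls with TMM, 76.8% with total counts and 89.6% with upper quartile scaling, which moved the median log2 change of all rows by 0.18 and 0.33.

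The copper list, miRNAs that act on copper proteins, moved upward at 7 dpi. Of its 7 hairpins 3 rose, 0 fell and 4 did not pass, while 6 rose adjusted over the list alone. MIR398a rose 4.39-fold, from 73.5 ± 58.8 to 323 ± 20.9 CPM, MIR408 rose 3.99-fold, from 1737 ± 1942 to 6925 ± 1358 CPM, and MIR397b rose from 0.326 ± 0.307 to 1.74 ± 0.162 CPM, beside 424 CPM in J2. MIR398b and MIR398c, which share a mature sequence, did not pass, at log2 2.14 each, with all 3 gall libraries above all root libraries. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.00604 for MIR398a, 0.0471 for MIR408 and 0.119 for MIR398b. None of the 7 passed without root replicate 3, gall replicate 1 or gall replicate 3, where the edgeR adjusted p of MIR398a was 0.0710, 0.0921 and 0.0685, that of MIR408 was 0.257, 0.195 and 0.225, and that of MIR397b was 0.0896, 0.120 and 0.165; 6 passed without root replicate 1, root replicate 2 or gall replicate 2. MIR408 was also lost with relative log expression (0.0871), no filter (0.0529), a mean count of 50 (0.156) or all 12 plant libraries in a fit (0.0902), and MIR397b in that last fit (0.0724). The list's median log2 change was 2.13 and stayed above 0 under every scaling. Camera placed it above the other rows (adjusted p = 8.65e-05), with adjusted p = 0.591 with an estimated correlation.

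The phosphate list, miRNAs of phosphate starvation, moved downward at 7 dpi. Of its 10 hairpins 4 fell and 0 rose, and 6 fell adjusted over the list alone. MIR399c fell 4.25-fold, from 119.7 ± 62.1 to 28.2 ± 16.2 CPM, MIR399f fell from 203 ± 52.1 to 71.9 ± 17.0 CPM, and MIR399a and MIR399b had log2 changes of −1.61 and −1.80. For MIR399c edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.00698, and 0.125 without gall replicate 1. That of MIR399f was 0.00698 by the same edgeR test, 0.0592 without gall replicate 1 and 0.0672 without gall replicate 3. Likewise MIR399b lost its call without gall replicate 1 (0.155) or gall replicate 3 (0.0586), and MIR399a without root replicate 3 (0.0882) or gall replicate 3 (0.0885). With all 12 plant libraries in a fit MIR399a (0.162) and MIR399f (0.138) did not pass. The count fell to 1 without gall replicate 1 or gall replicate 3 and was 7 without root replicate 2. Its median log2 change was −1.07, below 0 under every scaling, and camera gave an adjusted p of 0.000278, with adjusted p = 0.591 with an estimated correlation.

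The auxin list split at 7 dpi. Its 2 MIR390 hairpins rose and 4 of its 14 hairpins fell, with 3 higher and 6 lower adjusted over the list alone. The fallers included MIR160b and MIR160c, whose mature miR160 represses auxin response factors and has the same sequence in both: MIR160b (chromosome 4, 9888982 to 9889070) went from 54501 ± 13354 to 23003 ± 2163 CPM, 2.37-fold lower. The 4 lower calls became 3 with total counts and 0 with upper quartile scaling, 7 without root replicate 2, 1 without gall replicate 2, and 0 without root replicate 3, gall replicate 1 or gall replicate 3. For MIR160b the adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0178, and 0.0805, 0.185, 0.0600 and 0.0785 without root replicate 3 and gall replicates 1, 2 and 3.

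In the MYB and TCP list at 7 dpi, 2 of 6 hairpins rose and 1 fell, also adjusted over the list alone. MIR159a, from the family that represses GAMYB-like factors, rose from 134 ± 51.5 to 315 ± 53.5 CPM and MIR159b from 52.6 ± 26.8 to 141 ± 30.3 CPM. MIR159c held most of the family's counts, at 44830.2 ± 21046 CPM in roots and 71828 ± 8756 CPM in galls, and did not pass (log2 0.68). MIR319b, whose family represses TCP factors, fell from 352 ± 79.7 to 146 ± 50.8 CPM, while MIR319a and MIR319c did not pass (log2 −0.72 and −0.14). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment MIR159a had an adjusted p of 0.0296, and 0.0805, 0.0813, 0.0513 and 0.160 without root replicate 3 and gall replicates 1, 2 and 3. Without root replicate 3, gall replicate 1 or gall replicate 3 the edgeR adjusted p of MIR159b was 0.0710, 0.103 and 0.182, and that of MIR319b was 0.146, 0.148 and 0.110. With a mean count of 50 the 3 calls were lost, at 0.0682 for MIR159a, 0.0891 for MIR159b and 0.0703 for MIR319b, and MIR319b was lost with upper quartile scaling or all 12 plant libraries. The list had 3 higher and 1 lower without root replicate 1, 2 and 2 without root replicate 2, 1 and 1 without gall replicate 2, and 0 calls without root replicate 3, gall replicate 1 or gall replicate 3. Mature miR159 sequences are near-identical, so the division among copies is uncertain.

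Other lists at 7 dpi held few calls. In developmental timing 2 of 19 hairpins fell and 0 rose, also adjusted over the list alone: MIR156e went from 1163 ± 559.8 to 365 ± 77.3 CPM and MIR156d had a log2 change of −1.17, and neither passed without gall replicate 1 or gall replicate 3 (edgeR adjusted p 0.151 and 0.0866 for MIR156e, 0.287 and 0.198 for MIR156d). MIR156d also lost its call under every scaling but TMM among all rows, in limma-voom, with a mean count of 50, with all 12 plant libraries and without root replicate 1 (0.0526). The timing list had 1 lower without root replicate 1, 2 higher and 3 lower without root replicate 2, and 1 of each with upper quartile scaling, where its median turned positive. In the immunity list 1 of 9 rose and 1 fell (1 and 2 adjusted over the list alone). MIR825 rose from 0.460 ± 0.166 to 1.63 ± 0.424 CPM, beside 79.1 CPM in J2, and MIR163, which acts on methyltransferase genes, fell 2.71-fold, from 205 ± 97.7 to 75.5 ± 29.3 CPM. MIR163 lost its call without root replicate 3, gall replicate 1 or gall replicate 3, with edgeR adjusted p of 0.244, 0.238 and 0.105. It was also lost with upper quartile scaling (0.0728), a mean count of 50 (0.105) or all 12 plant libraries (0.0693). The immunity list had 2 higher and 1 lower without root replicate 1 and 1 higher and 3 lower without root replicate 2. MIR825 kept its call without root replicate 2 and lost it without each of the other 5 libraries (edgeR adjusted p 0.0867, 0.0591, 0.114, 0.147 and 0.0993 without root replicates 1 and 3 and gall replicates 1, 2 and 3), with relative log expression (0.0518) and in DESeq2 (0.104). Among the DCL4-made miRNAs 1 of 3 fell (2 adjusted over the list alone), MIR869 at log2 −1.27, a call lost without root replicate 1, root replicate 3, gall replicate 1 or gall replicate 3 (edgeR adjusted p 0.117, 0.257, 0.296 and 0.225), with the other 3 scalings of all rows, in limma-voom, with a mean count of 50 and with all 12 plant libraries. No member passed among 5 silencing, 6 sulfate and 15 nitrogen hairpins, 0 of each adjusted over the list alone, nor among 16 growth hairpins (2 lower adjusted over the list alone) and 4 siRNA triggers (2 higher adjusted over the list alone). Exceptions were 4 growth hairpins lower without root replicate 2, 1 siRNA trigger higher without root replicate 1, and 1 nitrogen hairpin higher without root replicate 1 or root replicate 3. Among 733 structural RNA rows 14 rose and 7 fell (1 and 4 adjusted over the list alone). Camera placed that list below the miRNA rows (adjusted p = 0.000112; adjusted p = 0.591 with an estimated correlation), a call lost without root replicate 2 (adjusted p = 0.310). Camera ranked its tRNA part below the other rows (adjusted p = 1.03e-07) and its snoRNA part above them (1.73e-05), with adjusted p = 0.454 and 0.677 with an estimated correlation. The list's median of −0.13 turned to 0.04 with total counts and 0.19 with upper quartile scaling.

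**Figure D1:**
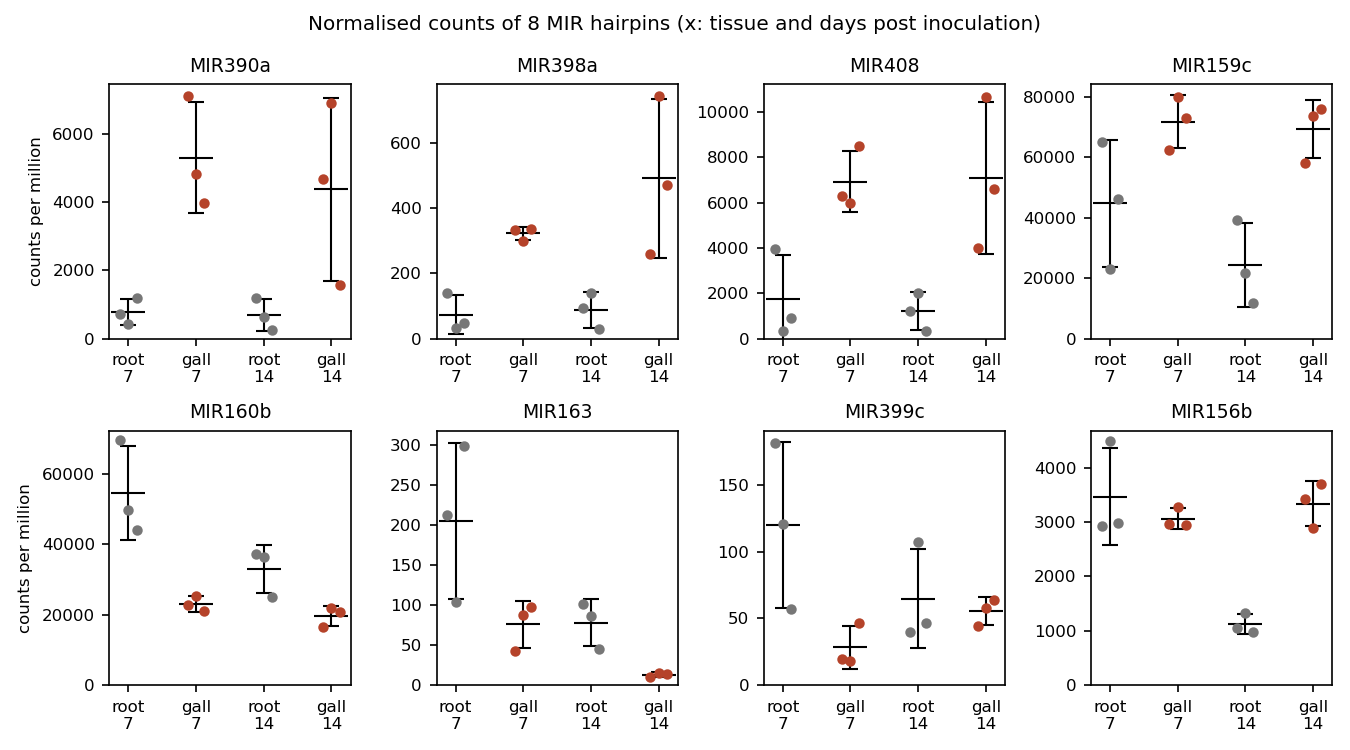
Normalised counts (CPM, linear axes from 0) of 8 hairpins in roots (grey) and galls (red) at 7 and 14 dpi, with 1 point per library and bars for the mean ± SD of 3 libraries. MIR390a averaged 770.3 CPM in roots and 5306 CPM in galls at 7 dpi, and MIR163 averaged 77.5 and 12.9 CPM at 14 dpi.

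The comparison at 14 dpi asked the same question of older galls. MIR390a rose again, from 693 ± 478 to 4385 ± 2684 CPM (6.33-fold), with MIR390b at 4.78-fold. MIR167d (chromosome 1, 11137539 to 11137915), of a family that represses auxin response factors, rose 4.59-fold, from 1549 ± 753 to 7106 ± 2521 CPM. MIR159c (chromosome 2, 18994632 to 18994856) rose 2.85-fold, from 24310.3 ± 13849 to 69234 ± 9620.4 CPM. MIR163 fell 5.96-fold, from 77.5 ± 29.3 to 12.9 ± 2.85 CPM, and MIR822 (chromosome 5, 897020 to 897356), a young miRNA made by DCL4, fell 4.38-fold, from 1161 ± 381 to 265 ± 202 CPM. In each of these rows all 3 gall libraries lay beyond all 3 root libraries. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, log2 changes were 2.66 (SE 0.57, adjusted p = 0.00462) for MIR390a, 1.51 (SE 0.36, adjusted p = 0.00842) for MIR159c and −2.57 (SE 0.37, adjusted p = 0.000804) for MIR163. These 6 hairpins kept their calls in every alternative that tested them, each library left out included.

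Of 996 rows tested at 14 dpi, 397 passed, 232 higher and 165 lower, and 485 had an unadjusted p under 0.05. They comprised 80 higher and 11 lower of 261 miRNA hairpins, 134 higher and 153 lower of 658 tRNA genes, 15 higher and 1 lower of 67 snoRNAs, 1 of 3 snRNAs and 2 of 5 rRNA rows. The share of calls that were higher was 58.4% with TMM, 73.5% with total counts and 71.3% with upper quartile scaling, which moved the median log2 change of all rows by 0.25 and 0.23. With miRNA rows scaled among themselves, 39 hairpins were higher and 33 lower of 256, so that 54.2% of the miRNA calls were higher instead of 87.9%, and the median log2 change of miRNA rows was −0.13 instead of 0.46. The hairpins called lower numbered 6 without root replicate 1, 4 without root replicate 2, 19 without root replicate 3, 5 without gall replicate 1 and 7 without gall replicate 2. snoRNA calls higher numbered 28 without root replicate 1, 3 without root replicate 2, 8 without root replicate 3 (2 lower) and 8 without gall replicate 1. tRNA calls numbered 170 without root replicate 1, 176 without root replicate 3 and 191 without gall replicate 3.

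The copper list stood higher at 14 dpi as well. Of 6 hairpins tested 5 rose and 0 fell, and 6 rose adjusted over the list alone. MIR398b and MIR398c rose 8.43-fold and 8.45-fold, MIR398b from 346 ± 254 to 2916 ± 1962 CPM, and MIR408 rose 5.91-fold, from 1199 ± 843 to 7088 ± 3369 CPM. For MIR398b and MIR408 edgeR's quasi-likelihood test gave Benjamini-Hochberg adjusted p of 0.00257 and 0.00387. MIR397a, at log2 1.67, lost its call without root replicate 1, root replicate 3 or gall replicate 2 (edgeR adjusted p 0.0771, 0.112 and 0.233) and with miRNA rows scaled among themselves (0.131), relative log expression (0.0547) or all 12 plant libraries (0.0655). The median log2 change of the list was 2.53, above 0 under every scaling. Camera gave an adjusted p of 0.00658, with adjusted p = 0.975 with an estimated correlation.

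The sulfate list, the MIR395 hairpins of sulfate starvation, rose at 14 dpi in 6 of 6 members, also adjusted over the list alone. MIR395f went from 15.3 ± 6.97 to 47.4 ± 16.5 CPM (3.08-fold), and the log2 changes of the others ran from 1.10 for MIR395e to 1.25 for MIR395c. The 6 hairpins carry 2 mature sequences, so they are not separate observations. The count was 0 of 6 with miRNA rows scaled among themselves, where the median was 0.60 instead of 1.21. It was 1 with all 12 plant libraries in a fit, 3 without root replicate 1 and 1 without gall replicate 2, and without root replicate 3 MIR395d and MIR395e lost their calls (edgeR adjusted p 0.0551 and 0.0535). Camera gave an adjusted p of 0.00971, with adjusted p = 0.975 with an estimated correlation.

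The auxin list split again, with 5 of 14 hairpins higher and 4 lower, and 5 higher and 8 lower adjusted over the list alone. Its median log2 change was −0.73 and its mean 0.10. Risers were MIR390a, MIR390b, MIR167d and MIR164b (217 ± 51.5 to 441 ± 88.2 CPM) among others, and MIR160b fell from 32933 ± 6779 to 19742 ± 2852 CPM (log2 −0.74). The lower calls became 0 with total counts or upper quartile scaling and 9, beside 3 higher, with miRNA rows scaled among themselves. They numbered 1 without root replicate 1, 0 without root replicate 2 or gall replicate 1, 2 without gall replicate 2 and 6 without gall replicate 3, and the higher calls numbered 3 without root replicate 3. For MIR160b the edgeR adjusted p was 0.0387, and 0.115, 0.134, 0.137 and 0.108 without root replicates 1 and 2 and gall replicates 1 and 2. MIR164b lost its call without root replicate 3 (log2 0.85), with miRNA rows scaled among themselves (log2 0.50) and with all 12 plant libraries (log2 0.97).

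In the MYB and TCP list 4 of 6 hairpins rose and 0 fell, also adjusted over the list alone. They were MIR159a (3.60-fold, 76.7 ± 41.1 to 275 ± 27.5 CPM), MIR159b (2.44-fold), MIR159c and MIR319c (464 ± 324 to 1123 ± 218 CPM). MIR319a (log2 0.15) and MIR319b (log2 −0.59) did not pass. With miRNA rows scaled among themselves 2 rose, and MIR159b (log2 0.83) and MIR319c (log2 0.90) no longer passed. MIR319c also lost its call without root replicate 2, root replicate 3 or gall replicate 2, at log2 1.27, 0.86 and 1.12. Without gall replicate 3 there were 4 higher and 2 lower, and MIR319a turned to log2 −1.04 (adjusted p = 0.0482 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

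In developmental timing 5 of 19 hairpins rose at 14 dpi and 0 fell, also adjusted over the list alone. MIR156b, a copy of the miR156 that represses SPL factors, rose from 1116 ± 186 to 3336 ± 409 CPM (2.99-fold), MIR157b from 1191 ± 527 to 4058 ± 1171 CPM, and MIR157c and MIR157d had log2 changes of 1.58 and 1.68. No other MIR156 hairpin was among the 5. Stretches of 21 nt in MIR156b occur at a median of 1 place in the genome and at up to 4605, beside at most 6 for MIR156e. A share of 0.0675 of those in MIR156b occurs at 5 or more places. Reads from repeat loci are therefore not excluded for MIR156b. MIR157d went from 13.8 to 44.0 CPM and held 4891 CPM in J2. With miRNA rows scaled among themselves 1 of the 19 passed and the list's median turned from 0.31 to −0.36; MIR156b then stood at log2 1.02 with an edgeR adjusted p of 0.0517. The counts were 3 without root replicate 2 or root replicate 3, and 3 higher with 1 lower without gall replicate 3. MIR157c lost its call in all 3 of these fits, at log2 1.43, 1.42 and 0.83. In the growth and meristem list 4 of 16 rose and 1 fell, also adjusted over the list alone, with a median of −0.21, which turned to 0.03 with total counts, and a mean of 0.14. MIR394a and MIR394b, whose miRNA acts on an F-box gene of meristem maintenance, rose 2.91-fold and 2.92-fold, MIR166e rose 2.43-fold, and MIR165b fell (log2 −0.83). With miRNA rows scaled among themselves 0 rose and 3 fell, and MIR165b lost its call with total counts or upper quartile scaling and without root replicate 1, root replicate 2, gall replicate 1 or gall replicate 3 (log2 −0.81, −0.73, −0.79 and −0.77), while 2 growth hairpins fell without root replicate 3 or gall replicate 2.

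Of the 3 DCL4-made miRNAs 2 fell at 14 dpi, also adjusted over the list alone: MIR822 and MIR839, the latter from 589 ± 527 to 203 ± 76.5 CPM. MIR839 lost its call without root replicate 1 (log2 −0.56), root replicate 2, gall replicate 1 or gall replicate 2 (−1.67, −1.45 and −1.87), with total counts or upper quartile scaling, in limma-voom and with a mean count of 50. In the immunity list MIR163 alone of 9 fell and 0 rose, also adjusted over the list alone, while 1 rose beside it with total counts or upper quartile scaling and 2 fell without root replicate 1 or gall replicate 2. MIR2111a rose among 10 phosphate hairpins, where 0 passed adjusted over the list alone, from 70.0 ± 45.1 to 204 ± 151 CPM, and its edgeR adjusted p of 0.0485 became 0.0668, 0.0940, 0.0671 and 0.133 without root replicates 2 and 3 and gall replicates 2 and 3. It was also lost with relative log expression (0.0637), no filter (0.0529), a mean count of 50 (0.0704), the top row left out (0.0510), all 12 plant libraries (0.0511) and miRNA rows scaled among themselves (0.137). Without root replicate 3 the phosphate list had 3 lower and 0 higher, and without root replicate 1 or gall replicate 1 it had 2 higher. MIR400 rose among 4 siRNA triggers (2 adjusted over the list alone), from 156 ± 33.2 to 290.4 ± 96.7 CPM, a call kept without gall replicate 1 and lost without each of the other 5 libraries (edgeR adjusted p 0.0701, 0.0620, 0.116, 0.0891 and 0.141 without root replicates 1, 2 and 3 and gall replicates 2 and 3), with relative log expression (0.0541), all 12 plant libraries (0.152) or miRNA rows scaled among themselves (0.455). No silencing or nitrogen hairpin passed, of 5 and 15, also adjusted over the list alone, but 1 and 6 fell with miRNA rows scaled among themselves, and 2 nitrogen hairpins fell without root replicate 3.

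tRNA genes moved both ways at 14 dpi. Among proline tRNA genes Pro-TGG-38 (chromosome 1, 10108710 to 10108781) went from 2407 ± 715 to 594 ± 131 CPM, 4.05-fold lower, Pro-AGG-8 fell from 2061 ± 552 to 548 ± 125 CPM and Pro-CGG-5 from 893 ± 114 to 277 ± 53.5 CPM. Phe-GAA-15 rose 2.19-fold, from 279 ± 55.6 to 611 ± 79.3 CPM, and Ile-TAT-5 rose 2.13-fold; both stood far higher in J2, at 20751 and 10485 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, log2 changes were −2.02 (SE 0.31, adjusted p = 0.000804) for Pro-TGG-38 and 1.13 (SE 0.27, adjusted p = 0.00852) for Phe-GAA-15, and these 5 rows kept their calls in every alternative run that tested them. By anticodon, 40 of 46 Pro-TGG rows fell, and 62 of 75 Tyr-GTA rows rose while 1 fell, families that were chosen after their values were seen and were not tested for enrichment. The tRNA rows higher and lower numbered 49 and 121 without root replicate 1, 75 and 123 without root replicate 2, 58 and 118 without root replicate 3, 76 and 156 without gall replicate 1, 109 and 99 without gall replicate 2, and 73 and 118 without gall replicate 3. Copies share reads, so rows of an anticodon are not separate observations. Among 733 structural RNA rows 152 rose and 154 fell (158 and 156 adjusted over the list alone), which became 217 and 109 with total counts and 209 and 116 with upper quartile scaling, so the balance turned. Camera placed the list below the miRNA rows (adjusted p = 7.48e-07), with adjusted p = 0.975 with an estimated correlation. Camera ranked the tRNA part below the other rows (adjusted p = 7.06e-11) and the snoRNA part above them (2.70e-05), with adjusted p = 0.359 and 0.805 with an estimated correlation.

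**Figure D2:**
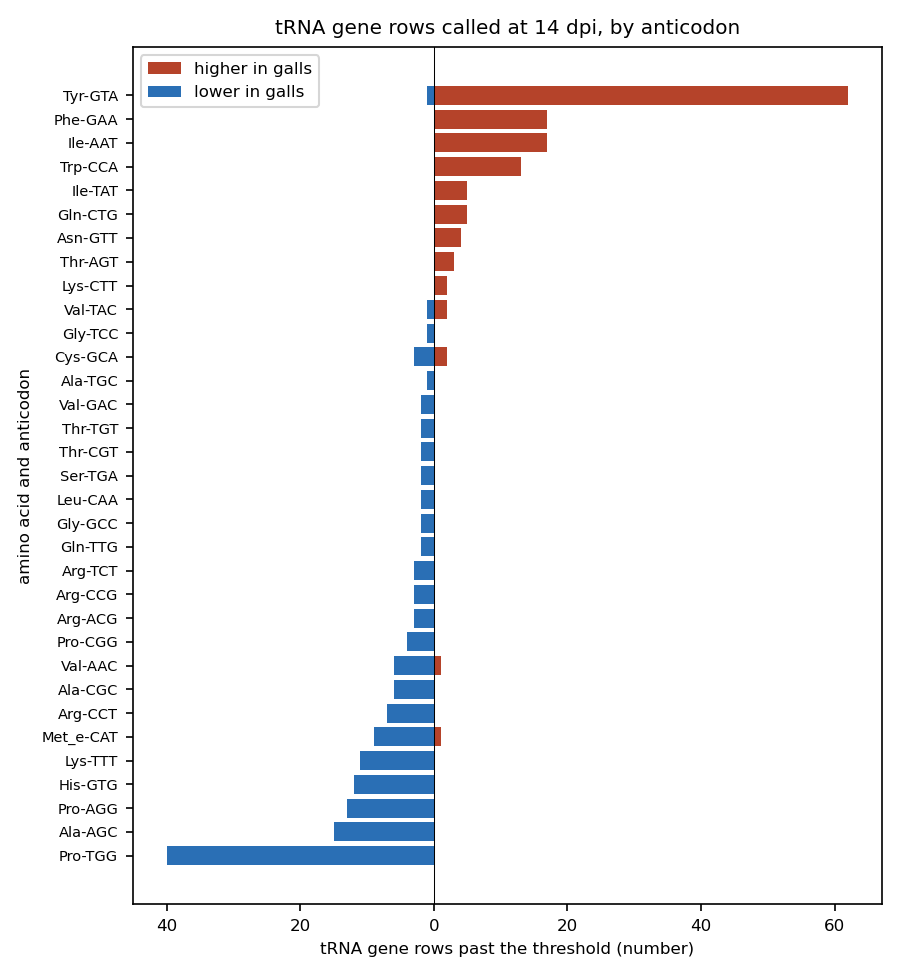
Number of tRNA gene rows past the threshold at 14 dpi for each of 33 anticodons with such a row, higher in galls to the right (red) and lower to the left (blue). Of 46 Pro-TGG rows 40 were lower and of 75 Tyr-GTA rows 62 were higher with TMM scaling; over all anticodons 134 rows were higher and 153 lower, against 183 and 109 with total counts.

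The gall effects of the 2 days were compared over the rows tested on both. Hairpins higher in galls on both days numbered 36, beside 11.4 for independent lists, and included MIR390a, MIR398a, MIR408, MIR159a, MIR775, MIR414 and MIR5641. Hairpins lower on both days numbered 6, beside 0.892 for independent lists, and included MIR160b, MIR163 and MIR5020c, which at 14 dpi lost its call without root replicate 2 or gall replicate 2 (edgeR adjusted p 0.0787 and 0.0589). Over 994 rows of all types 49 were higher and 10 lower on both days, beside 12.03 and 4.65 for independent lists, and 0 were called in opposite directions. The log2 changes of the days had a Pearson correlation of 0.726 and a Spearman correlation of 0.695 across rows, which are not independent replicates. Among 259 hairpins, 17 passed at 7 dpi alone, 47 at 14 dpi alone and 42 on both. The roots of each day are separate libraries, so no control is shared between the days.

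**Figure D3:**
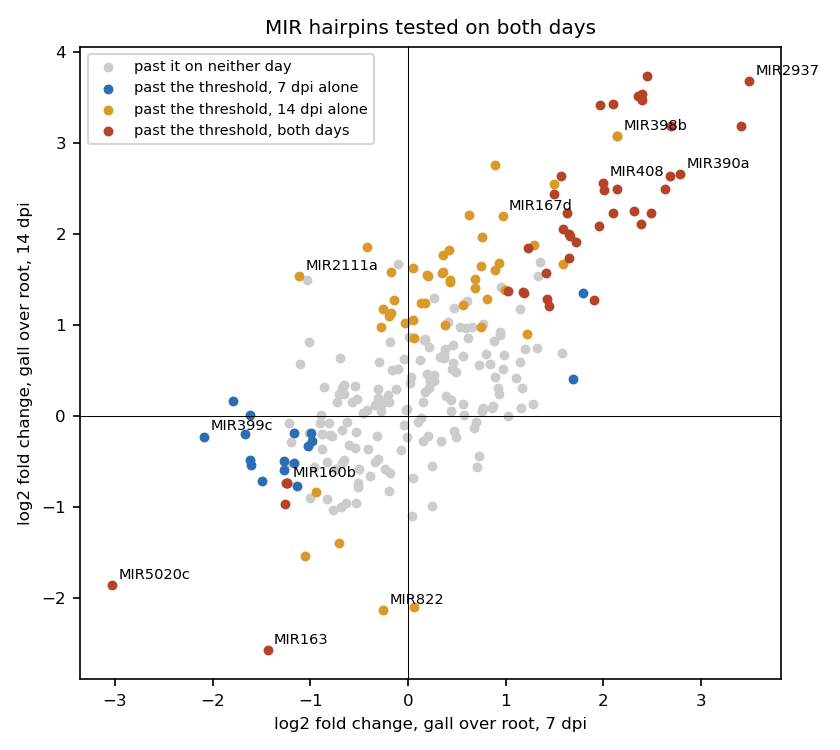
Log2 fold change of gall over root at 7 dpi (x) and at 14 dpi (y) for 259 hairpins tested on both days, coloured by the days on which they passed the threshold. MIR390a lies at 2.78 and 2.66, MIR163 at −1.44 and −2.57, and 42 hairpins passed on both days.

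Whether the gall effect differs between the days was tested directly. The rows of lowest p were MIR156b, with a difference of 1.58 (SE 0.39) on the log2 scale, Pro-TGG-38 (−1.38, SE 0.43), Pro-CGG-5 (−1.46), MIR447c (−2.36) and Pro-AGG-8 (−1.36). MIR156b changed by −0.18 at 7 dpi and 1.58 at 14 dpi, and MIR399c by −2.09 and −0.22. MIR390a differed by −0.25 (SE 0.73). None of 1014 rows passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where MIR156b had an adjusted p of 0.182, 191 rows had an unadjusted p under 0.05 (164 of them tRNA genes and 25 miRNA hairpins), limma-voom called 0 and DESeq2 called 81 while it left 609 of the 1014 rows without an adjusted p. So calls on a single day, those of MIR399, MIR395 and MIR157 hairpins included, were not shown to differ between the days over all rows. Adjusted over the list alone, 1 timing hairpin and 4 phosphate hairpins passed, all with a higher log2 change at 14 dpi, and 0 in each other list of miRNA families and in the structural RNA list. Of these 5 hairpins MIR156b did not pass without gall replicate 1 of 7 dpi (adjusted p = 0.0523 over its list by the edgeR test) or root replicate 1 of 14 dpi (0.0582). Of the 4 phosphate hairpins, MIR399b, MIR399c, MIR2111a and MIR2111b, 2 passed without gall replicate 1, gall replicate 3 or root replicate 3 of 7 dpi or gall replicate 2 of 14 dpi. None of the 4 passed without gall replicate 2 or root replicate 1 of 7 dpi, or without gall replicate 3, root replicate 1 or root replicate 3 of 14 dpi.

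The J2 libraries were compared with the 7 dpi roots to see which rows hold counts in nematode samples. The origin of those reads is not settled by this comparison. The root and gall CPM given here carry TMM factors and the J2 CPM do not, while the test scaled both groups by total counts. Glu-TTC-11, a mitochondrial tRNA gene, held 55610.0 ± 50754 CPM in J2 and 467 ± 199 CPM in roots, Ser-GCT-7 held 23330.2 ± 29792 and 393 ± 112 CPM, and Phe-GAA-15 held 20751 ± 18224 and 378 ± 91.2 CPM. MIR5658, which lies in a coding exon, held 11485 ± 7461 CPM in J2 and 10.4 ± 0.682 CPM in roots. The 5.8S rRNA rows AT3G41979.1 and AT2G01020.1, identical in counts, were lower in J2, at 13742 ± 3611 beside 83520.0 ± 17657 CPM. Of 1009 rows tested 577 differed from the 7 dpi roots, 330 higher and 247 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in which MIR5658 had a log2 difference of 10.19 (SE 0.96, adjusted p = 3.37e-07). Among hairpins 132 were higher and 64 lower, and among snoRNAs 5 higher and 26 lower. Several hairpins that rose in galls stood higher still in J2, such as MIR2937 (198 CPM on average) and MIR4243 (68.6 ± 8.20 CPM), whereas MIR390a (749.5 ± 416 CPM) and MIR408 (1191 ± 546 CPM) stood in J2 below their level in galls. The J2 libraries held 77650 to 221736 counts, so the J2 values of MIR2937 and MIR4243 rest on few counts. Their SD may understate the error. MIR5658 itself rose in galls at 7 dpi from 10.4 ± 0.682 to 28.1 ± 5.20 CPM, a call lost without gall replicate 1 or gall replicate 3 (edgeR adjusted p 0.0592 and 0.0526).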

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

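Of the tests in this part, those of explanations and of other splits were chosen after the results had been seen. MIR156b drew attention because its gall effect differed between the days: the difference was 1.58 on the log2 scale (SE 0.39), with −0.18 at 7 dpi and 1.58 at 14 dpi. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment its adjusted p was 0.0157 over the developmental timing list alone and 0.182 over all rows. The adjusted p over its list lay above 0.05 without gall replicate 1 of 7 dpi (0.0523) and without root replicate 1 of 14 dpi (0.0582), and at most 0.0473 without each other library. Each day was read in a table of its own, so a difference between the days cannot be told apart from a difference between the tables' runs. If the days were swapped on the labels, the difference would change its sign. Stretches of 21 nt in MIR156b occur at a median of 1 place in the genome. Some occur at up to 4605 places, so reads from repeat loci are not excluded.

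In the phosphate list 4 hairpins differed between the days in the same way, adjusted over the list alone. They were MIR399b, by 1.82 (adjusted p = 0.0318 by edgeR's quasi-likelihood test), MIR399c, by 1.72 (0.0435), MIR2111a, by 2.54 (0.0318), and MIR2111b, by 2.40 (0.0318). Over all rows their adjusted p values were 0.195, 0.223, 0.190 and 0.195. Both MIR399 hairpins stood lower in galls at 7 dpi, and MIR2111a had log2 changes of −1.11 and 1.54 on the days. For MIR399c the adjusted p over the list was 0.0740 and 0.113 without gall replicates 2 and 3 of 14 dpi, 0.108 and 0.0670 without gall replicates 1 and 2 of 7 dpi, 0.121 and 0.109 without root replicates 1 and 3 of 14 dpi, 0.0859 without root replicate 1 of 7 dpi and 0.0523 with upper quartile scaling. MIR399b was lost without the same libraries, at 0.0604, 0.113, 0.0683, 0.0501, 0.0959, 0.0892 and 0.0859. MIR2111a and MIR2111b, which share a mature sequence, both had 0.113 without gall replicate 3 of 14 dpi, 0.0501 and 0.0508 without gall replicates 2 and 3 of 7 dpi, 0.0656 and 0.0892 without root replicates 1 and 3 of 14 dpi, and 0.0556 and 0.0864 without root replicates 1 and 3 of 7 dpi. No biological explanation was tested.

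Over all rows the difference of days called 0 with edgeR, 0 with limma-voom and 81 with DESeq2, which left 609 of 1014 rows without an adjusted p, and 191 rows had an unadjusted p under 0.05. With a real count of 0, all 100 of 100 splits drawn within each day must give as many, so they say nothing about chance. The highest other split, with 380, kept the galls of 7 dpi and exchanged galls for roots at 14 dpi, which by construction turns the difference into a sum of the 2 gall effects.

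The spike-in cel-mir-54, a row outside the comparisons, held 617 counts in J2 replicate 1, equal to 0.277% of that library's counts, and at most 8 in any other library. The spike-ins cel-mir-39 and cel-mir-238 held at most 6 and 20 counts in any library. No explanation was tested for it.

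Among hairpins, 36 were higher in galls on both days, 21 of them from under 10 CPM in roots. For 11 of the 36 the tables argue against nematode reads with the composition of the J2 libraries as the source. These 11 would need more than 100% of the gall counts from nematodes at 7 dpi. No verdict is drawn for the set as a whole, which falls into 2 groups. At 7 dpi 24 of the 36 had a higher CPM in J2 than in galls and would need at most 27.9%. The other 12 would need at least 80.1%. The 36 would need a median of 12.2% of the gall counts from nematodes at 7 dpi. Such percentages set gall and root CPM with TMM factors against J2 CPM scaled by totals alone. Of the 50 rows highest in J2 over roots (8 of the 36 included), 90% allow at most 3.42%. Members of the 36 set that limit, between MIR831 (3.35%) and MIR5020b (4.06%), and the highest of the 50 outside the 36 allows 1.54%. The 11 hairpins that would need more than 100% include MIR390a, MIR408 and MIR398a. With miRNA rows scaled among themselves the median log2 change at 14 dpi of the 35 tested was 1.66 (median SE 0.39), beside 2.23 with all rows. The 36 were chosen by their rise in these same data, so a median without a rise was hardly possible. This test therefore does not decide on scaling to structural RNA rows as a cause. Of the 25 hairpins that need less than 100%, 7 need no more than 3.42%, MIR5658 (0.155%) and MIR414 (2.74%) among them. By that limit nematode reads stay open for these 7, though MIR414 lies above 1.54%. The rest of the 25 exceed the limit, from 3.46% for MIR3932a to 80.1% for MIR159b. No conclusion is drawn for single rows among them, since the J2 CPM of rare hairpins rest on few counts. The calls of 9, MIR775 and MIR159b among them, were lost at 14 dpi among miRNA rows alone, where 26 kept theirs. These 9 then had log2 changes from 0.637 to 1.58. At 7 dpi all 36 passed among miRNA rows alone. Scaling stays open, and a plant response is an untested hypothesis.

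The tests of these 36 were reworked after their values were known. An earlier test of scaling, which asked that more than 27 of the 36 keep their call at 14 dpi for scaling to be argued against, left scaling open at 26 of 36, and the test by the median log2 change of 1.66 replaced it. The need for nematode reads was also computed for all hairpins called higher, chosen after the values were seen. At 7 dpi 10 of 41 hairpins, MIR397b (0.333%) and MIR825 (1.48%) among them, needed no more than the 3.42% allowed, and at 14 dpi 13 of 80, with MIR157d at 0.617%. Among tRNA rows it was 0 of 11 at 7 dpi and 16 of 134 at 14 dpi, Phe-GAA-15 (1.60%) and Ile-TAT-5 (2.19%) among them. For these rows nematode reads stay open. No limit was computed from the 14 dpi libraries, so the rows of both days were held against the limit that members of the 36 set at 7 dpi. Among the 50 rows behind it, the highest outside the 36 allowed 1.54%. MIR397b, MIR825 and MIR157d lie under that value, while Phe-GAA-15 and Ile-TAT-5 lie above it.

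Plant hairpins took counts in the J2 libraries: 88 hairpins with a mean plant count above 1000 had a median of 0.299%, 0.212% and 0.259% of their plant count in J2 replicates 1 to 3. The tables argue against RNA of the tomato plants on which the nematodes were raised as the main source, since 12 Brassicaceae-specific hairpins such as MIR158a and MIR775 (chosen after their values were seen) had a median of 0.228% and 55 conserved ones 0.254%, a ratio of 0.899. Reads from root and gall libraries of the same table may be a source and stay open, with a Spearman correlation of 0.741 between J2 and plant counts over hairpins, and 0.679 with the 14 dpi libraries. Nematode RNA that matches these rows was not tested.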

How the results depend on the processing

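Of the alternatives here, the fit to miRNA hairpins scaled among themselves was chosen after seeing the data. For named genes, 1753 values at 7 dpi and 1736 at 14 dpi kept direction and side of the threshold, 112 and 119 lost their call, and 66 and 39 gained it; values never past the threshold count among those kept. Of the named calls, 13 of 41 at 7 dpi and 40 of 71 at 14 dpi held in every alternative that tested them, and 28 and 31 were lost in some. MIR319a alone turned, to −1.04 at 14 dpi without gall replicate 3, in a range from −1.04 to 0.56 without 1 library (0.15 with all); the cause was not tested. Depth was not varied, so its limit was not separated from the spread between libraries; data simulated at these depths recovered 45.8% (7 dpi) and 40.9% (14 dpi) of log2 changes of 1.

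At 7 dpi (83 called; miRNA 41 higher, 21 lower; tRNA 18) the values that moved over 1.5 times were these. Total counts gave 13 miRNA lower, upper quartile 69 higher and 8 lower, and no filter 9 tRNA. A mean count of 50 gave 43 called, with 16 miRNA higher and 9 lower. Rows summed per family gave 53 called of 303, with 3 tRNA. With rows high in nematodes left out, 7 rows were left, which explains 0 called, 0 miRNA higher, 0 lower and 0 tRNA. miRNA rows only gave 33 miRNA lower, and 12 libraries in one fit gave 7. Without 1 library, called ranged from 17 to 176, miRNA higher from 15 to 54, lower from 1 to 49 and tRNA from 0 to 66. Except for the 7 rows, the cause was not tested.

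At 14 dpi (397 called; miRNA 80 higher, 11 lower; tRNA 287) total counts gave 5 miRNA lower, upper quartile 5, and DESeq2 17. A mean count of 50 gave 49 miRNA higher. Rows summed per family gave 62 called of 291, with 39 miRNA higher, 6 lower and 12 tRNA. With rows high in nematodes left out, 18 rows were left, with 0 called, 0 miRNA higher, 0 lower and 0 tRNA. miRNA rows only gave 72 called, 39 higher and 33 lower. Without 1 library, called ranged from 268 to 341, miRNA higher from 54 to 94, lower from 4 to 19 and tRNA from 170 to 232. The difference of days gave 81 with DESeq2, which left 609 rows without an adjusted p, and 0 without any 1 library. J2 against roots (577) ranged from 398 to 590. The lists called by camera numbered 3 on each day, 0 with an estimated correlation and 0 with fry on both days, and 3 to 4 (7 dpi) or 3 to 5 (14 dpi) without 1 library. The cause was not tested.

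A replicate block gave 53 called at 7 dpi, with 33 miRNA higher, 11 lower and 6 tRNA. It gave 326 at 14 dpi, 538 for J2 and 0 for the difference of days. Named calls lost with the block are given here alone, with their edgeR adjusted p. At 7 dpi they were MIR156d (0.0542), MIR159a (0.0542), MIR163 (0.0522), MIR397b (0.0592), MIR825 (0.120), MIR831 (0.0723) and MIR869 (0.114). At 14 dpi they were MIR160b (0.132), MIR160c (0.135), MIR400 (0.0537), MIR839 (0.0576), MIR2111a (0.0923) and His-GTG-4 (0.0577). No label says that the replicate numbers pair the samples. Same-numbered galls and roots correlated at −0.149, −0.0504 and 0.249 at 7 dpi and −0.0821, 0.395 and −0.158 at 14 dpi. Not every sample correlated best with its own number, and with 3 libraries per group these correlations cannot decide on pairing.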

Other observations

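All tests of explanations and of other splits in this part were chosen after the results had been seen. Calls among tRNA genes at 14 dpi are given here by anticodon, without a test of enrichment: 62 of 75 Tyr-GTA rows, 17 of 17 Phe-GAA rows, 17 of 17 Ile-AAT rows and 13 of 15 Trp-CCA rows were higher in galls. Lower were 40 of 46 Pro-TGG rows, 13 of 15 Pro-AGG rows, 15 of 16 Ala-AGC rows and 12 of 12 His-GTG rows. Summed per anticodon at the scaling of the rows, the log2 change was −1.44 for Pro-TGG, −1.49 for His-GTG, −1.37 for Ala-AGC, 0.73 for Tyr-GTA, 1.13 for Phe-GAA and 1.06 for Trp-CCA. The families named were chosen after their values were seen, and 16 of 51 families passed as sums.

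Of the 287 tRNA rows called at 14 dpi 256 held distinct counts, but distinct rows can be near-identical. Tyr-GTA-24 and Tyr-GTA-28, for example, averaged 552.23 and 552.27 CPM in roots and both 956.0 CPM in galls. As single rows, 243 of the 287 kept call and direction with total counts, 250 with upper quartile scaling and 279 with relative log expression. For counts summed per anticodon, 16 families passed at the scaling of the rows, 6 higher and 10 lower. With a scaling of their own 12 passed and 0 were higher, so Tyr-GTA, Phe-GAA and Trp-CCA no longer passed. Scaling therefore stays open as a cause of the rises. Such near-identical copies are each counted, so the 287 calls are not as many separate changes. Whether reads shared between gene copies also raise the share of rows called stays open. Of 51 anticodon families 31.4% passed as sums at the scaling of the rows and 23.5% with a scaling of their own, against 43.6% of single rows. The lower share of families has no spread to set it against, which keeps this open. No biological explanation was tested.

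A minority of snoRNA rows passed, 3 of 67 at 7 dpi and 16 of 67 at 14 dpi. At 14 dpi U49.1 had a log2 change of 2.00 (SE 0.36, adjusted p = 0.00147 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), SNOR105 of 1.59, AT1G03746 of 1.52 and U3D of 1.01, while AT2G17295 fell, at −1.09. These genes were chosen after their values were seen. At 7 dpi SNOR77 rose by 1.64, SNOR105 by 1.15 and AT1G74453 by 1.27, with 0 snoRNAs called without gall replicate 3, 1 without gall replicate 1 or root replicate 1, and 7 without root replicate 2. Of 67 snoRNAs 15 were higher and 1 lower at 14 dpi, 31 and 0 with total counts, and 24 and 0 with upper quartile scaling. The number higher was 28 without root replicate 1, 3 without root replicate 2, 8 without root replicate 3 and 8 without gall replicate 1. Camera placed the snoRNA rows above the others at 7 dpi (adjusted p = 1.73e-05) and 14 dpi (2.70e-05), with adjusted p = 0.677 and 0.805 with an estimated correlation.

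Other splits of the same 6 libraries into 3 and 3 were fitted in the same way. The real split called 83 rows at 7 dpi, 397 at 14 dpi and 577 for J2 against roots, the highest other split called 0 in each of these by edgeR's quasi-likelihood test, and 1 of 10 splits gave as many rows in each; 10 splits are too few for a share under 0.05. For lists tested with camera, 9 of 10 splits at 7 dpi and 8 of 10 at 14 dpi called as many as the real 3, with 11 and 8 lists in the highest other split. Of 9 other splits at 7 dpi, 9 called the structural RNA list, 4 the copper list and 4 the phosphate list, and at 14 dpi 8 called structural RNA, 4 copper and 4 sulfate. Most groupings that mix galls and roots thus called as many lists as the real one, and the reason was not tested.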
